A study of Rattus norvegicus with 4 samples.

How the data were processed

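Esophagi of male Sprague-Dawley rats were taken at day 7 or day 14 after X-ray exposure, and those of 5 animals were pooled into 1 sample per group, per the labels. The labels' protocol records cold storage in tissue storage solution and shipment to the processing laboratory, digestion with collagenase I, DNase I and trypsin, straining and removal of dead cells with a kit. Single cells were captured with the 10x Genomics Chromium 3' chemistry, which tags each captured transcript with a UMI, and sequenced on an Illumina NovaSeq instrument. The authors deposited 1 matrix of raw UMI counts per library over 32623 features, with no normalization. The submitters' processing notes name Cell Ranger 5.0.0 and the builds mRatBN7.2 and rn7, and the gene annotation release is not given in the sources used here. Gene names were those paired with the identifiers in the matrices, and counts of features sharing a symbol were summed. Of 687 symbols listed as markers or list members, 44 did not match a feature name and were not analysed here. No coordinates were used.

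Cells were kept with at least 200 genes, at least 500 UMIs and at most 20% of UMIs from mitochondrial genes, and the deposited barcodes already held at least 500 UMIs each. Doublets were called per library with Scrublet in scanpy at its automatic threshold, at an expected rate of 0.8% per 1000 cells. It marked 3.76%, 3.03%, 2.28% and 3.98% of cells in the control, single-dose, fractionated day 7 and fractionated day 14 libraries, which were left out. The expected shares were 9.45%, 7.79%, 7.26% and 8.06% in the same order, so uncalled doublets may remain. Counts were log-normalised to 10000, and the libraries were clustered together without integration on 2000 variable genes, 30 principal components and 15 neighbours with shared-neighbour weights, by the Leiden method at resolution 1.0. Of 41 clusters, 33 received a class name, 5 stayed unnamed and 3, in which over 50% of cells were called doublets, were removed. Remaining calls were frequent in the mast and dendritic clusters, at 33.7% and 21.1%, before those cells were left out.

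A cluster took the name of the class with the highest mean standardised marker expression among 21 marker lists. It stayed unnamed if its 10 leading genes by fold held more markers of another class than of its own, if fewer than 3 markers were at least 2-fold higher, or if its cells were shallow and no marker was among the leading genes. Class names stand for cells like that type, and immune cells are those of clusters whose best-scoring class was immune. This scoring and a further margin of 0.25 between the best and second scores were set after the data were seen. The margin kept out cluster 21, between macrophage and dendritic cells, at 0.0798%, 3.05%, 5.08% and 0.271% of cells in the 4 libraries, and cluster 24, between mural and blood endothelial cells, at 2.70%, 0.498%, 0.440% and 3.42%. Immune or stress genes led some named clusters, including Csf3 and Lcn2 in endothelial cluster 3, Fosl1 and Ccl20 in epithelial cluster 8 and Ccl20 in epithelial cluster 13. Cluster 27, named T/NK/ILC, also held the mast cell gene Mcpt1l1 among its leading genes. Shares have exact Clopper-Pearson 95% intervals, and ratios of shares exact intervals from the conditional binomial distribution.

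Expression was read from raw counts summed per library and class, as CPM, in classes with at least 200 cells in both libraries of a comparison. The stress list alone was also read against the control in every named class with at least 50 cells in both libraries. Ratios have exact conditional binomial 95% intervals. A library with 0 counts was set to a floor of 3 counts to form a ratio. For such genes the fold is given as at least the bound of the exact interval. Gene lists were summarised as the median log2 ratio over members with at least 20 UMIs in the pair of libraries, with an interval from 500 Poisson redraws of the counts. Each median was placed among 10000 random lists of the same size matched on mean expression. Named genes were the 3 higher and the 3 lower per class and comparison with the largest fold, ranked by the interval bound nearest to 1, among genes with at least 50 UMIs. They had to pass a free RNA rule, judged in the library where the gene was higher. CPM in the class had to be at least 0.5 times its highest CPM in any other named class of at least 100 cells there. Classes of that size differed between libraries, so higher and lower members were not filtered alike. A median over passing members can shift through this selection alone. Mitochondrial, ribosomal protein and haemoglobin genes and features without a symbol were left out. Besides these, up to 4 members of each list with the largest fold by the same ranking could be named. For shares of cells with a UMI of Mki67 or Top2a, each cell was thinned to 1000 UMIs.

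The groups, 4 comparisons, 21 gene lists, marker lists, filters, naming rule for genes and the alternatives for filter, doublets, resolution, class assignment, scaling, count minimum and cell weight were fixed before the data were examined. The comparison of fractionated day 14 with control cells, the p53 list without 8 stress-responsive members, medians over members passing the free RNA rule (at least 3), fibroblasts with cluster 25, macrophages with cluster 21, the comparison of cluster 21, all alternatives for fibroblast and macrophage shares and those for named genes other than scaling and the stricter filter, with all alternatives for the added comparisons, were chosen after seeing the data. Lists for T cell cytotoxicity and effector genes, for T regulatory, type 2 and type 17 genes and for G2/M genes in T/NK/ILC cells were not computed, since that class had under 200 cells in every library. Fibroblast lists, including matrix and myofibroblast genes, could be read in the named clusters of the fractionated day 14 and control libraries, and in the single-dose library with cluster 25 counted. The calculation of ratios was tested on simulated data in which 200 genes were given a 2-fold change. It recovered 96.5% of them among 11738 genes for epithelial cells of the single-dose and control libraries, with 95.2% of intervals covering the true ratio. For blood endothelial cells of the fractionated day 7 and control libraries it recovered 96.0% among 8444 genes, with 96.0% coverage. For macrophages of the single-dose and control libraries it recovered 65.0% among 8554 genes, with 96.2% coverage. The simulated counts held Poisson error only, the error that the intervals assume, so coverage near 95% was built in. Variation between cells or animals was not simulated. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.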

Results

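Single-cell RNA sequencing was carried out on dissociated rat esophagus from 4 groups of irradiated or unirradiated male animals, with the esophagi of 5 rats pooled into 1 library per group. The control pool received 5 fractions of 0 Gy and was collected at day 7, the single-dose pool received 1 X-ray dose of 35 Gy and was collected at day 7, and the fractionated pools received 5 doses of 7 Gy and were collected at day 7 or day 14. The libraries held 12505, 11488, 10887 and 10468 barcodes with 97207745, 109618791, 59805782 and 80574775 unique molecular identifiers (UMIs) in that order. After filtering, 11278, 9445, 8872 and 9597 cells were kept, with median depths of 6234, 5861, 5065 and 5831 UMIs. Because each group was a single pool, no difference has a replicate check, no test was made, and intervals in parentheses are 95% intervals that cover counting error only. List medians are log2 ratios of CPM, the counts summed over the cells of a class and scaled to a common total, and percentiles place a list among 10000 random lists matched on expression, as a description of these libraries.

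**Figure D1:**
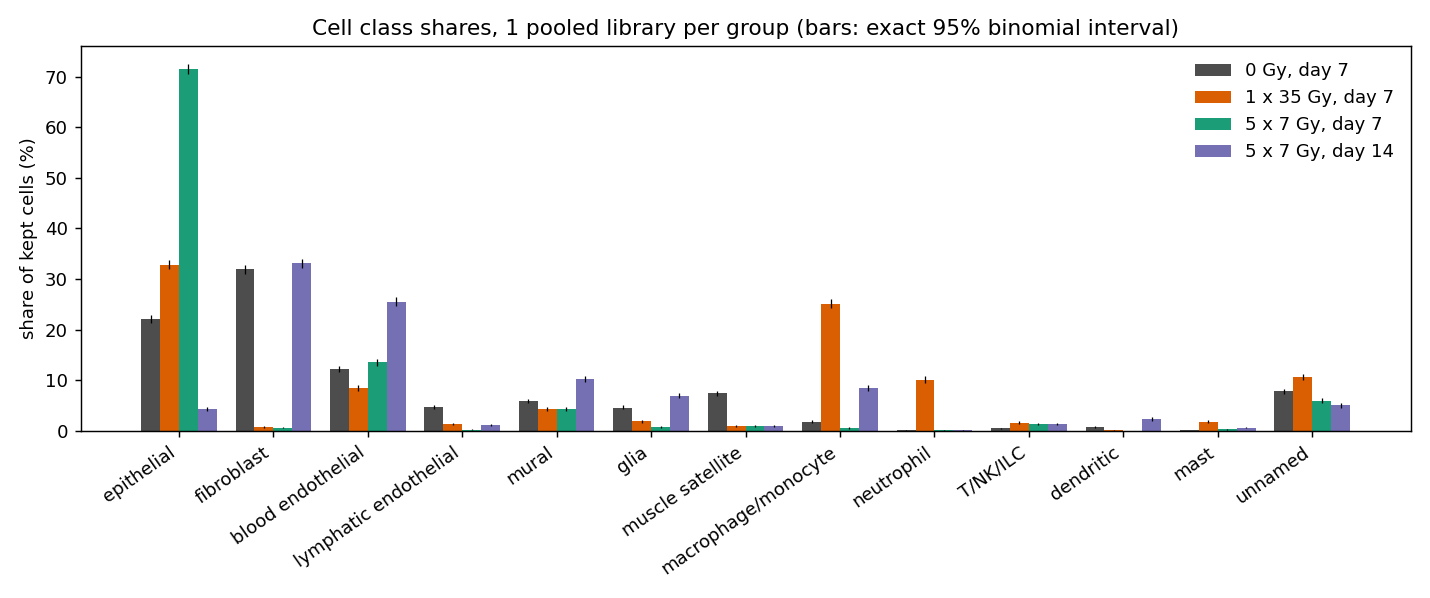
Share of kept cells (vertical axis, percent) in each named cell class and in the unnamed clusters, for the 4 pooled libraries (colours), with exact binomial intervals. Fibroblasts made up 31.9% of control and 33.1% of fractionated day 14 cells but under 1% in both irradiated day 7 libraries, or 7.15% of single-dose cells if the unnamed cluster 25 is counted with them.

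The first comparison set the single 35 Gy dose against no radiation at day 7. Immune cells made up 42.5% of the single-dose library and 3.37% of the control, a share 12.6-fold (11.3 to 14.04) higher. Macrophages and monocytes were 13.7-fold (11.9 to 15.9) higher, at 25.1% against 1.84%. Neutrophils, the granulocytes recruited early to damaged tissue, were 114-fold (61.9 to 239) higher, at 10.1% against 0.0887%. Fibroblasts were 39.7-fold (31.6 to 50.5) lower. They were 4.47-fold (4.11 to 4.86) lower, at 7.15% against 31.9%, with the unnamed cluster 25, which scored highest for fibroblasts, counted among them. The unnamed cluster 23 also scored highest for fibroblasts, with erythroid genes among its leading genes, and was left out of both counts for its shallow depth. It held 5.01% of control and 0.0847% of single-dose cells, so counting it would take both ratios further from the control, by an amount not computed. Muscle satellite cells were 7.97-fold (6.39 to 10.04) lower and lymphatic endothelial cells 3.48-fold (2.86 to 4.27) lower. Epithelial cells were 1.49-fold (1.42 to 1.57) higher, at 32.9% against 22.02%, and blood endothelial cells 1.44-fold (1.32 to 1.57) lower. Shares were taken after enzymatic dissociation and dead cell removal, and 15.2% of single-dose barcodes against 5.49% of control barcodes had been left out for a high mitochondrial share. With the stricter cell filter the log2 ratio of epithelial shares was 0.26 instead of 0.58.

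In epithelial cells, genes of DNA replication were higher after the single dose. All 42 measured S phase genes were higher, with a median log2 ratio of 0.72 (0.64 to 0.75) at percentile 100. The replication licensing factor Cdc6 stood at 2.19 (1.86 to 2.52), the chromatin assembly subunit Chaf1b at 1.40 (1.17 to 1.65) and the helicase subunits Mcm5 and Mcm6 at 1.30 (1.16 to 1.45) and 1.13 (1.02 to 1.24). The G2/M list was also higher, at 0.31 (0.28 to 0.37) at percentile 93.4, with 37 of 49 members higher, among them the ubiquitin-conjugating enzyme Ube2c at 1.04 (0.99 to 1.09). Epithelial differentiation genes were lower at -0.71 (-0.77 to -0.69) at percentile 0, with 23 of 28 lower. Among them, the suprabasal keratin Krt4 stood at -1.77 (-1.79 to -1.75), while the cornified envelope genes Sprr2d and Sprr1b were higher at 4.57 (2.67 to 7.64) and 2.47 (2.07 to 2.89). Basal genes had a median of 0.24 (0.21 to 0.30), p53 targets -0.11 (-0.39 to 0.020), NRF2 targets -0.37 (-0.45 to -0.29), hypoxia and glycolysis genes -0.046 (-0.13 to 0.042) and wound keratins and alarmins -0.38 (-0.58 to -0.28). Of the 19 measured members of this last list, 6 were at least 2-fold higher and 7 at least 2-fold lower, so its median gives no shared direction. In the p53 list Btg2 at -3.90 (-3.93 to -3.86) and Plk3 at -3.76 (-3.88 to -3.64) were lowest, and the cell cycle inhibitor Cdkn1a stood at -2.68 (-2.74 to -2.62). The carbonic anhydrase Car2 was 680-fold (398 to 1277) higher, Nat8l 342-fold (94.5 to 2828) and Cd177 108-fold (29.6 to 894). The neuropeptide gene Calcb was 201-fold (85.6 to 621) lower, the transcription factor gene Egr4 75.9-fold (46.4 to 134) and Igfbp3 52.7-fold (45.5 to 61.4).

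Immediate-early and heat shock genes, listed as the dissociation and stress response, were lower in the same epithelial cells at -2.74 (-2.85 to -2.66) at percentile 0, and inflammatory mediators were lower at -0.89 (-1.17 to -0.66). The stress list held Atf3 at -9.47 (-9.64 to -9.31) and Egr1 at -4.27 (-4.31 to -4.23). Mediators held Tnfaip3 at -5.73 (-6.61 to -4.96), Nfkbia at -3.75 (-3.78 to -3.71) and Cxcl6 at 5.31 (3.43 to 8.38). Cxcl6 led cluster 25, so it may be free RNA. Interferon-stimulated genes had a median of 0.35 (0.092 to 0.46) and MHC class II genes of 2.20 (2.02 to 2.39), and at most 1 measured member of either list passed the free RNA rule in epithelial cells in each of the 4 comparisons. Of the stress genes 1 passed it here, and over passing members inflammatory mediators stood at -2.29, p53 targets at -1.52 and wound keratins and alarmins at -1.44. The alarmins S100a9 and S100a8, at 12.65 (11.10 to 14.93) and 9.75 (9.22 to 10.34), did not pass it. Clusters 13, 16 and 19 held most single-dose epithelial cells and clusters 8, 20 and 29 most control ones, and Car2 was the leading gene of cluster 16. Relative to all other cells, the wound keratin Krt17 was among the leading genes of clusters 13, 16 and 19, and Krt16 among those of cluster 16. The median of all genes itself lay at 0.15, and the G2/M median was 0.16 with median-of-ratios scaling, 0.12 with every cell weighted equally and 0.66 with the stricter filter. Without the 8 p53 targets that other stress pathways also induce, the p53 median was 0.073 (0.00047 to 0.14), and -0.46 (-1.18 to -0.24) over passing members. Wound keratins and alarmins stood at -0.067 with the stricter filter, and basal genes at 0.47 with that filter and 0.094 with median-of-ratios scaling. Hypoxia and NRF2 medians were 0.20 and -0.24 over passing members.

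Cells with a UMI of the proliferation genes Mki67 or Top2a, counted after thinning each cell to 1000 UMIs, made up 14.7% (13.3 to 16.2) of control and 18.7% (17.4 to 20.1) of single-dose epithelial cells. The fractionated shares were 9.72% (8.99 to 10.5) at day 7 and 11.9% (8.91 to 15.5) at day 14. In mural cells, a contractile class taken as background, the thinned shares were 1.54%, 2.65%, 0.325% and 1.22% in group order. Without thinning the epithelial shares were 31.7%, 47.5%, 16.6% and 31.03%, at median depths of 15171, 18758, 6672 and 13256 UMIs, against mural depths of 3689, 5033, 1652 and 4884. Thinning left out 43, 27, 160 and 16 epithelial cells.

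In blood endothelial cells the cell cycle lists were lower after the single dose. G2/M genes stood at -1.19 (-1.34 to -1.06) at percentile 0, with 32 of 46 at least 2-fold lower, including Cks2 at -2.58 (-2.89 to -2.29) and Mki67 at -1.999 (-2.31 to -1.70). S phase genes stood at -0.88 (-1.002 to -0.61), including the ribonucleotide reductase subunit Rrm2 at -2.67 (-3.79 to -1.70). Interferon-stimulated genes were lower at -0.89 (-1.03 to -0.54) at percentile 0, with Ifit1 at -3.37 (-5.31 to -1.91) and Rsad2 at -2.90 (-3.86 to -2.07). Endothelial activation genes were higher at 0.63 (0.36 to 0.75) at percentile 99.7, including the leukocyte adhesion molecules Selp and Sele at 2.29 (2.21 to 2.37) and 2.09 (1.94 to 2.24) and the granulocyte growth factor Csf3 at 4.15 (3.91 to 4.41). p53 targets had a median of -0.24 (-0.56 to 0.054), within which Aen, Ccng1 and Phlda3 were higher at 3.19 (2.70 to 3.72), 2.89 (2.51 to 3.28) and 2.43 (2.25 to 2.62) and Btg2 was lower at -2.93 (-3.01 to -2.86). Angiogenesis and tip cell genes had a median of -0.20 (-0.36 to -0.13), with Cxcr4 at -3.46 (-4.13 to -2.86) and Esm1 at -3.23 (-3.73 to -2.76). The stress list stood at -2.65 (-2.83 to -2.55) and inflammatory mediators at -0.73 (-0.81 to -0.64). P2ry6 was 48.5-fold (24.4 to 113) higher, Slamf7 50-fold (22.7 to 137) and the prostaglandin transporter Slco2a1 22.3-fold (17.9 to 28.1). Fam71a, with 0 counts in the single-dose library, was at least 34.5-fold lower, Egr1 29.1-fold (26.7 to 31.7) and Irf1 24.1-fold (20.4 to 28.6). Cluster 3 held most single-dose and cluster 5 most control endothelial cells, and Selp, Sele, Csf3 and Slco2a1 were among the 10 leading genes of cluster 3. With doublets kept the G2/M and S phase medians were -0.45 and -0.34, and with every cell weighted equally inflammatory mediators stood at 0.082. At a minimum of 100 UMIs per gene the interferon-stimulated median was -0.47 and the S phase median -0.46. Without the 8 stress-responsive members the p53 median was 0.038 (-0.089 to 0.62).

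In macrophages and monocytes the genes of infiltrating monocytes were higher after the single dose and those of resident macrophages lower. Inflammatory monocyte genes stood at 3.31 (2.97 to 3.43) at percentile 100, with S100a8 at 6.55 (5.19 to 8.42) and the matricellular gene Thbs1 at 5.52 (3.97 to 7.80). S100a8 was also a leading gene of the neutrophil cluster 17, so free neutrophil RNA may enter its value. Of 17 measured members of the list, 10 passed the free RNA rule, at a median of 3.38. Tissue-resident genes stood at -3.03 (-3.14 to -2.72) at percentile 0, with the neonatal Fc receptor Fcgrt at -4.36 (-4.55 to -4.17) and F13a1 at -3.96 (-4.14 to -3.78). Hypoxia and glycolysis genes were higher at 0.90 (0.65 to 1.33), including the glycolytic enzymes Pkm at 2.77 (1.92 to 3.78), Pgk1 at 2.26 (1.95 to 2.59) and Ldha at 2.01 (1.84 to 2.19). Slpi was 117-fold (90.7 to 152) higher, Upp1 191-fold (52.8 to 1577) and Vcan 67.7-fold (47.9 to 98.96), and the leukotriene synthase Ltc4s was 451-fold (350 to 591) lower, Atf3 366-fold (316 to 427) and Cd83 125-fold (107 to 147). Medians were -1.23 (-1.42 to -0.96) for G2/M, -0.54 (-1.10 to -0.27) for p53 targets, -0.12 (-0.32 to 0.18) for interferon-stimulated genes, 0.55 (0.29 to 0.75) for NRF2 targets, -0.80 (-1.09 to 0.00088) for matrix proteases and 0.25 (0.18 to 0.60) for lipid-associated macrophage genes. Stress response genes lay at -3.62 (-3.66 to -3.58) and inflammatory mediators at -1.20 (-2.05 to -0.69). Among members passing the free RNA rule, medians were -3.73 for mediators, -1.52 for p53 targets, -1.44 for interferon-stimulated, 0.40 for protease and -2.35 for tissue-resident genes. They were also 0.066 for NRF2 targets, -0.75 for G2/M and 1.39 for hypoxia and glycolysis genes. Neutrophils, at 958 single-dose and 10 control cells, reached 100 cells only in the former, so they could exclude higher members only. Cluster 2 held nearly all single-dose cells of this class and cluster 15 nearly all control ones, with Plac8 and Vcan among the leading genes of the former and Ltc4s, Cd83 and F13a1 among those of the latter. MHC class II genes had a median of 0.41 (0.27 to 0.47), which was -1.30 at the lower clustering resolution. Weighting every cell equally gave 0.17 for that list and -0.78 for G2/M genes. NRF2 targets stood at 0.24 with doublets kept, and p53 targets at -0.40 (-0.65 to 0.16) without the 8 stress-responsive members. At a minimum of 100 UMIs mediators stood at -3.22, and at the lower resolution interferon-stimulated genes stood at 0.23 and lipid-associated genes at 0.76. The log2 ratio of Slpi was 5.03 instead of 6.86 at that resolution.

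The second comparison set 5 fractions of 7 Gy against no radiation at day 7. Epithelial cells made up 71.5% of the fractionated library, 3.25-fold (3.10 to 3.40) above the control, and immune cells 7.54%, 2.24-fold (1.97 to 2.55) above it. Fibroblasts were 52.4-fold (40.1 to 69.9) lower, lymphatic endothelial cells 24.3-fold (15 to 41.9) lower, muscle satellite cells 8.55-fold (6.77 to 10.95) lower and glia 6.19-fold (4.78 to 8.12) lower. Macrophages and monocytes were 3.19-fold (2.34 to 4.43) lower in the named clusters but 2.95-fold (2.51 to 3.48) higher, at 5.66% against 1.92%, with the unnamed cluster 21 counted, which scored highest for them with dendritic cells close behind. The log2 ratio of -1.68 became 1.61 with the stricter filter and 0.66 with each cell classed by its own markers, so no direction is given. Neutrophils stood at 0.0902% in a ratio of 1.02-fold (0.349 to 2.86), and blood endothelial cells at 13.6% in a ratio of 1.11-fold (1.03 to 1.20). Cluster 31, the one named dendritic, held 0 of 8872 cells, which allows a share of up to 0.0416% for that cluster, while cluster 21 held 5.08% of this library and cluster 39, left unnamed with dendritic markers among its leading genes, 0.169%. Barcodes over the mitochondrial limit made up 16.6% of this library.

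In fractionated epithelial cells the cell cycle lists were lower than in the control. S phase genes had a median of -0.80 (-0.92 to -0.72) at percentile 0, with 36 of 42 lower, including Dscc1 at -1.91 (-2.16 to -1.67) and the helicase subunit Mcm3 at -1.56 (-1.74 to -1.38). G2/M genes had one of -0.64 (-0.73 to -0.63), including Cks2 at -1.70 (-1.76 to -1.65) and Cdca8 at -1.55 (-1.65 to -1.45). Hypoxia and glycolysis genes were lower at -0.88 (-0.92 to -0.80), with the peptide hormone gene Adm at -7.48 (-7.85 to -7.13). Differentiation genes stood at -0.38 (-0.45 to -0.29), with Elf3 at -2.12 (-2.22 to -2.02) and the ammonia channel Rhcg at 3.65 (1.68 to 6.77). Basal genes stood at 0.29 (0.16 to 0.51), with the basal transcription factor Tp63 at 1.58 (1.51 to 1.64) and Krt14 at -1.45 (-1.51 to -1.39). Wound keratins and alarmins stood at -0.61 (-0.89 to -0.46), including the growth factor Areg at -4.45 (-4.59 to -4.32) and Ereg at -5.49 (-5.78 to -5.21). NRF2 targets stood at 0.0055 (-0.085 to 0.079), including the cystine transporter Slc7a11 at 2.11 (1.92 to 2.32). p53 targets had a median of -0.55 (-0.74 to -0.27), and of -0.029 without 8 members that other stress pathways also induce. Car2 was 65.9-fold (38.4 to 124) higher, Apoc3, with 0 control counts, at least 27.3-fold and Cd177 53.3-fold (14.5 to 445). The AP-1 gene Fosl1 was 580-fold (357 to 1014) lower, Egr4 at least 238-fold and Adm 178-fold (140 to 230). In the same cells the stress list lay at -4.59 (-4.65 to -4.49) at percentile 0, with Fos at -9.30 (-9.47 to -9.13), and inflammatory mediators at -4.58 (-5.09 to -4.18), with Cxcl1 at -9.70 (-10.38 to -9.11). Interferon-stimulated genes stood at 0.25 (0.059 to 0.40) and MHC class II genes at 1.81 (1.55 to 2.05). Of the stress genes 1 passed the free RNA rule, and over passing members inflammatory mediators stood at -2.53 and wound keratins and alarmins at -2.21. Clusters 1, 6 and 14 held most fractionated epithelial cells, at a median depth of 6672 UMIs against 15171 in the control. With every cell weighted equally p53 targets stood at -0.22, wound keratins and alarmins at -0.32, basal genes at 0.73 and interferon-stimulated genes at 0.504. Passing hypoxia and glycolysis genes stood at -0.54 and passing NRF2 targets at 0.16.

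Blood endothelial cells after fractionation had higher interferon-stimulated genes, at 0.47 (0.30 to 0.55) at percentile 99.2, with 26 of 34 higher, including the antiviral genes Mx1 at 2.64 (1.61 to 3.81) and Oas1a at 1.71 (1.36 to 2.06). G2/M genes were lower at -0.55 (-0.71 to -0.43) and S phase genes at -0.30 (-0.54 to -0.19), although Gtse1 stood at 3.33 (2.56 to 4.19). p53 targets had a median of 0.011 (-0.13 to 0.43), with Ccng1 at 2.82 (2.43 to 3.23) and Btg2 at -3.54 (-3.65 to -3.42), and of 0.59 without the 8 stress-responsive members. Angiogenesis genes stood at -0.0078 (-0.22 to 0.094). The adrenomedullin receptor subunit gene Ramp3 was 76.98-fold (20.7 to 645) higher, Sphkap 35.6-fold (13.4 to 134) and Slco2a1 14.9-fold (11.9 to 18.9), and Egr1 was 73.9-fold (62.6 to 87.9) lower, Jun 62.3-fold (55.2 to 70.7) and Gadd45b 61.6-fold (47.3 to 81.6). The stress median stood at -4.14 (-4.30 to -3.98) and inflammatory mediators at -2.53 (-2.96 to -2.19). Cluster 3 held most of these cells, the median of all genes lay at 0.13, and the endothelial activation median of -0.40 (-0.53 to -0.27) became 0.28 over members passing the free RNA rule, with mediators at -1.82 and the stress list at -5.53. G2/M genes stood at -0.23 with every cell weighted equally, -0.30 at the lower resolution and -0.36 over passing members. S phase genes stood at -0.18 with the stricter filter, and passing p53 targets at 0.52. Ramp3 had a log2 ratio of 3.33 instead of 6.27 under equal weighting.

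The third comparison set both schedules of the same total dose, 35 Gy, against each other at day 7. The fractionated library held 2.18-fold (2.08 to 2.27) the epithelial share of the single-dose library, and its immune share was 5.63-fold (5.19 to 6.12) lower. Macrophages and monocytes were 43.7-fold (33.1 to 58.9) lower, or 4.98-fold (4.53 to 5.49) lower with cluster 21 counted, and neutrophils 113-fold (56.9 to 261) lower. Blood endothelial cells were 1.60-fold (1.46 to 1.75) higher, glia 2.55-fold (1.91 to 3.43) lower and lymphatic endothelial cells 6.96-fold (4.18 to 12.3) lower. Mural and T/NK/ILC shares had ratios of 0.986-fold (0.855 to 1.14) and 0.831-fold (0.650 to 1.06), and fibroblasts one of 0.756-fold (0.524 to 1.09), but were 8.93-fold (6.99 to 11.6) lower with cluster 25 counted among them. In epithelial cells S phase genes were lower after fractionation at -1.45 (-1.57 to -1.38) at percentile 0, with 33 of 42 at least 2-fold lower, including Cdc6 at -2.71 (-3.08 to -2.36). G2/M genes were lower at -1.02 (-1.09 to -0.97), including the mitotic kinase Aurka at -1.99 (-2.14 to -1.85). Differentiation genes were higher at 0.38 (0.31 to 0.44) at percentile 99.9, with the transcription factor Grhl3 at 2.10 (2.02 to 2.18) and Sprr2d at -3.82 (-5.73 to -2.41). Wound keratins and alarmins were lower at -1.31 (-1.57 to -1.29), with Lcn2 at -5.47 (-5.91 to -5.06), although this list stood at -0.21 over members passing the free RNA rule. Apoc3 was at least 45.01-fold higher after fractionation, the kinase Wnk4 7.86-fold (7.11 to 8.71) and Ly6d 6.99-fold (6.76 to 7.23). The cytokine Il24 was 411-fold (114 to 3399) lower, Lipn 73.3-fold (31.2 to 227) and Ccdc96 at least 30.4-fold. Medians were -0.10 (-0.19 to -0.016) for p53 targets, -0.015 (-0.15 to 0.078) for interferon-stimulated, 0.014 (-0.12 to 0.20) for NRF2, -0.69 (-0.76 to -0.55) for MHC class II and -0.65 (-0.72 to -0.61) for hypoxia and glycolysis genes. For the stress list the median stood at -1.73 (-1.85 to -1.70), and at -0.95 over members passing the free RNA rule. Inflammatory mediators, of which 2 passed it, stood at -2.59 (-3.09 to -1.90). The G2/M median was -0.59 with every cell weighted equally, and the basal median of 0.28 (0.24 to 0.31) was -0.0055 with the stricter filter. Equal weighting also gave 0.22 for differentiation genes, -0.84 for wound keratins and alarmins and 0.64 for basal genes. NRF2 targets stood at 0.27 and basal genes at 0.17 over passing members.

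In blood endothelial cells interferon-stimulated genes were higher after fractionation than after the single dose at 1.16 (1.06 to 1.39) at percentile 100, with 19 of 32 at least 2-fold higher, including Rsad2 at 2.98 (2.11 to 3.96) and Ifi44l at 2.502 (1.81 to 3.26). Angiogenesis genes were higher at 0.51 (0.41 to 0.64), with Cxcr4 at 2.83 (2.18 to 3.53) and Esm1 at 2.33 (1.82 to 2.88), and endothelial activation genes lower at -0.48 (-0.65 to -0.35), with Il6 at -4.24 (-4.92 to -3.63). S phase genes stood at 0.49 (0.19 to 0.55), G2/M genes at 0.62 (0.48 to 0.79) and p53 targets at 0.024 (-0.16 to 0.15). The peptidase Enpep was 10.2-fold (6.42 to 17.04) higher and the death ligand Tnfsf10 6.57-fold (5.41 to 8.04). Y_RNA, a symbol shared by several near-identical features and so uncertain, was 13.5-fold (8.26 to 23.4) higher. Csf3 was 99.9-fold (60.5 to 179) lower, the neutrophil chemokine Cxcl1 43.6-fold (32.6 to 59.7) and Sod2 25.1-fold (22.4 to 28.1). The stress list lay at -1.17 (-1.46 to -1.06) and inflammatory mediators at -1.76 (-3.29 to -1.56), or at -0.60 and -0.82 over members passing the free RNA rule. The median of all genes lay at 0.14, and with doublets kept the S phase and G2/M medians were 0.043 and -0.012. At a minimum of 100 UMIs the S phase median was 0.066.

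**Figure D2:**
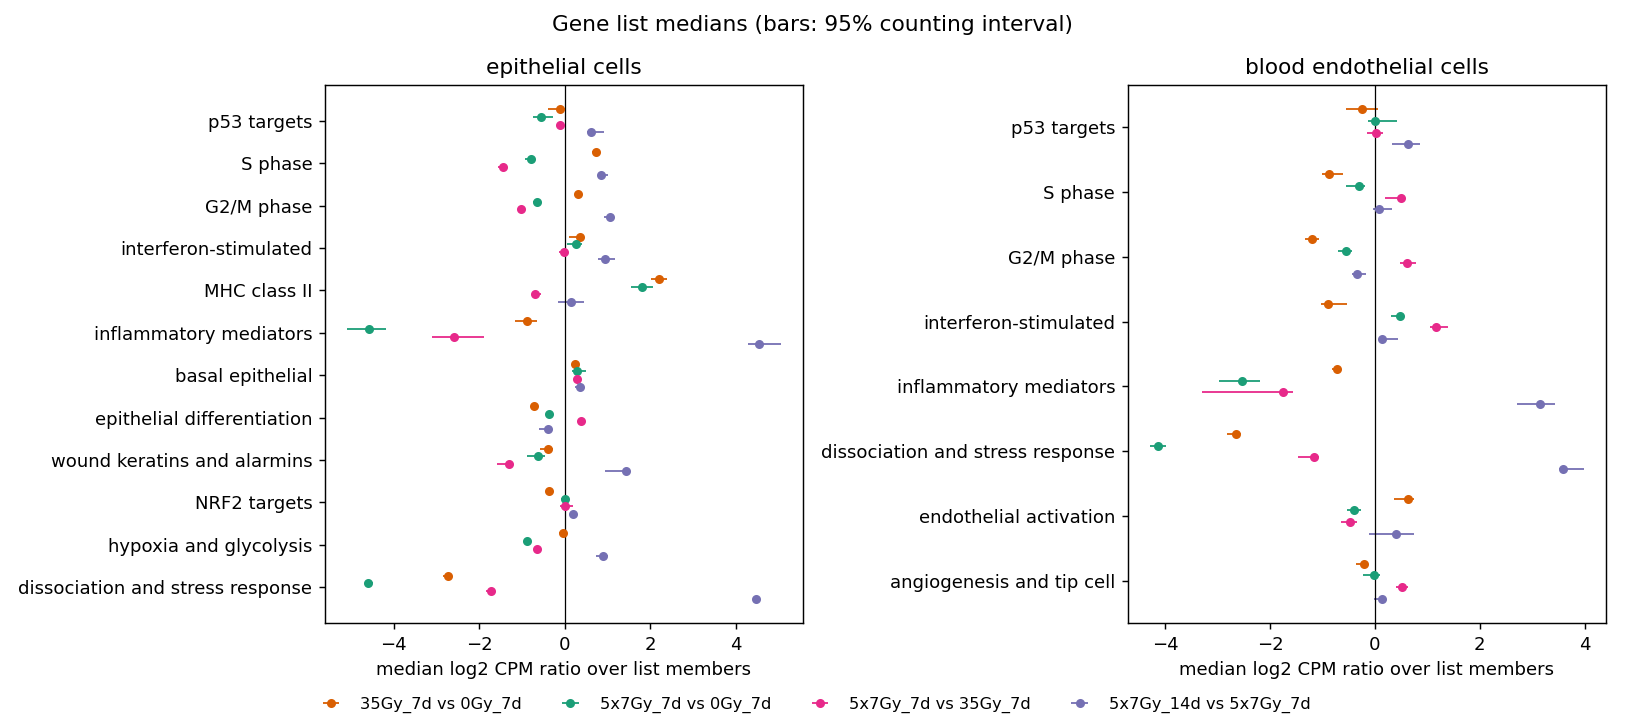
Median log2 CPM ratio (horizontal axis) of each gene list in epithelial (left) and blood endothelial cells (right), with points coloured by comparison and bars for the counting interval. The epithelial S phase median stood at 0.72 for the single dose against control and -0.80 for fractions against control, and the stress list at -2.74 and -4.59.

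The fourth comparison followed the fractionated schedule from day 7 to day 14. Epithelial cells were 16.4-fold (14.8 to 18.1) lower at day 14, at 4.37%, and fibroblasts 54.4-fold (41.6 to 72.5) higher, at 33.1%. Macrophages and monocytes were 14.6-fold (11 to 19.8) higher, or 1.53-fold (1.37 to 1.72) higher with cluster 21 counted, glia 9.36-fold (7.26 to 12.2), lymphatic endothelial cells 5.55-fold (3.30 to 9.89), mural cells 2.41-fold (2.14 to 2.72) and blood endothelial cells 1.88-fold (1.76 to 2.02). Immune cells were 1.74-fold (1.59 to 1.92) higher, at 13.2%, and muscle satellite cells had a ratio of 1.01-fold (0.731 to 1.39). In epithelial cells S phase genes were higher at day 14 at 0.85 (0.77 to 1.01), with Fen1 at 1.94 (1.57 to 2.30), and G2/M genes at 1.05 (0.93 to 1.09) at percentile 100, with Cdc20 at 2.13 (1.99 to 2.27). Krtdap, a gene of differentiating keratinocytes, was 6.65-fold (6.46 to 6.84) lower, Grhl3 7.49-fold (5.99 to 9.49) and Ly6g6e at least 5.78-fold. Wound keratins and alarmins were higher at 1.42 (0.94 to 1.46) at percentile 100, with Areg at 5.87 (5.73 to 6.02), and hypoxia and glycolysis genes at 0.89 (0.73 to 0.998). Atf3 was 4508-fold (3174 to 6636) higher, the natriuretic peptide gene Nppb 2402-fold (428 to 95202) and Egr4 at least 358-fold. Medians were 0.62 (0.52 to 0.90) for p53 targets, 0.94 (0.77 to 1.17) for interferon-stimulated, 0.18 (0.12 to 0.21) for NRF2 and 0.14 (-0.16 to 0.46) for MHC class II genes. Stress genes, of which 2 passed the free RNA rule, stood at 4.46 (4.39 to 4.53) and inflammatory mediators at 4.55 (4.29 to 5.05). Passing members had medians of 1.43 for mediators and -0.13 for NRF2 targets. Clusters 8, 20 and 29 held most of the 419 epithelial cells at day 14. With every cell weighted equally the G2/M median was 0.502, the differentiation median of -0.39 (-0.61 to -0.37) was 0.12 and the basal median of 0.37 (0.23 to 0.44) was -0.063. Equal weighting also put MHC class II genes at 0.57, and the log2 ratio of Krtdap at -1.62 instead of -2.73. Interferon-stimulated genes stood at 0.51 with the stricter filter, p53 targets at 0.40 (0.19 to 0.55) without the 8 stress-responsive members and hypoxia and glycolysis genes at 0.47 over passing members.

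Blood endothelial cells at day 14 had higher p53 targets than at day 7, at 0.63 (0.33 to 0.85) at percentile 100, with Sertad1 at 2.70 (2.496 to 2.91) and Plk3 at 3.08 (2.68 to 3.52), and the median was 0.34 without the 8 stress-responsive members. G2/M genes stood at -0.34 (-0.43 to -0.16), S phase genes at 0.080 (-0.036 to 0.33), interferon-stimulated genes at 0.15 (0.077 to 0.43), endothelial activation genes at 0.40 (-0.10 to 0.74) and angiogenesis genes at 0.14 (-0.013 to 0.19), the last with the placental growth factor Pgf at 3.57 (2.68 to 4.64). Atf3 was 253-fold (188 to 348) higher, the heat shock gene Hspa1b 245-fold (187 to 329) and Cxcl1 86.9-fold (65.2 to 119), and Sphkap was 9.65-fold (6.61 to 14.3) lower, Slco2a1 7.16-fold (6.39 to 8.03) and the endothelial transcription factor Sox18 6.55-fold (5.90 to 7.28). Beside these, the stress list stood at 3.58 (3.51 to 3.98) and inflammatory mediators at 3.15 (2.70 to 3.44), or at 4.93 and 2.16 over members passing the free RNA rule. Clusters 5 and 10 together held most day 14 and cluster 3 most day 7 cells, and the median of all genes lay at -0.14. G2/M genes stood at -0.63 over passing members and -0.12 with every cell weighted equally, which also gave 0.31 for angiogenesis and 0.0095 for interferon-stimulated genes. Passing S phase genes stood at -0.067, passing activation genes at 0.027 and passing angiogenesis genes at 0.026. Without the 8 stress-responsive members, passing p53 targets stood at 0.035 (-0.13 to 0.35).

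**Figure D3:**
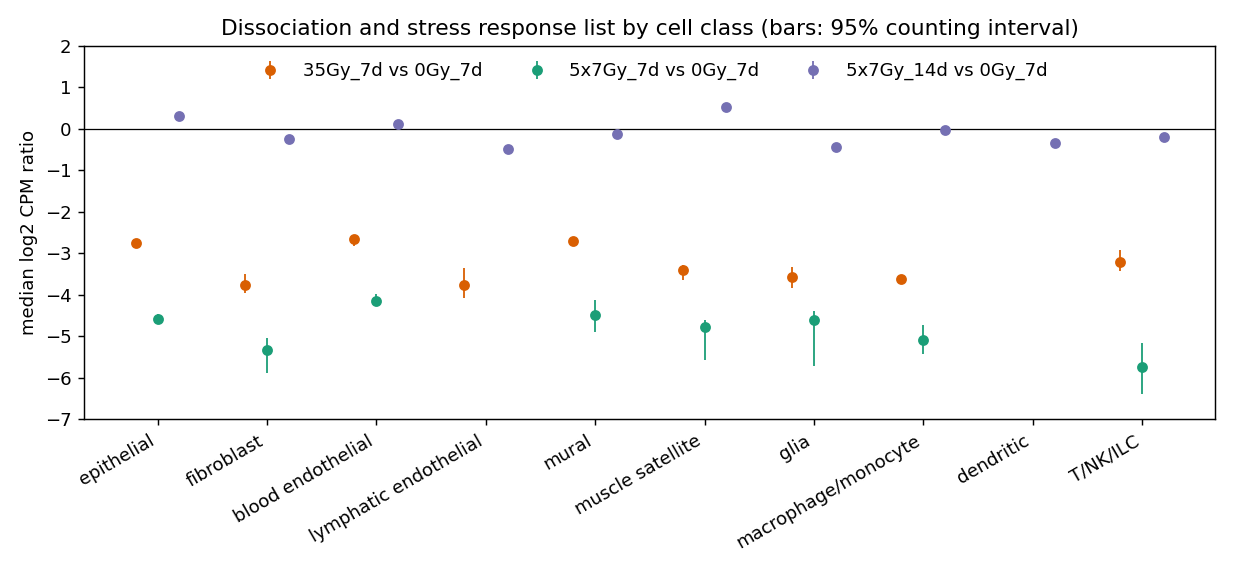
Median log2 CPM ratio of the dissociation and stress response list against the control (vertical axis) in each cell class with enough cells (horizontal axis), with points coloured by library and bars for the counting interval. The day 7 medians lay between -5.74 and -2.65 in the 17 pairs of class and irradiated library, and those of the fractionated day 14 library, a comparison added after the data were seen, between -0.48 and 0.54.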

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

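All values here were picked out after they were seen, and none of the differences was tested, since each group held 1 library. In 4 gene groups the single dose and the fractions lay on opposite sides of the shared control at day 7, with both counting intervals excluding 0. Epithelial S phase genes had a median log2 ratio of 0.72 after the single dose and -0.80 after fractions. Epithelial G2/M genes stood at 0.31 and -0.64 in the same order, although the former, at percentile 93.4 beside a median of all genes of 0.15, was 0.12 with every cell weighted equally and 0.16 with median-of-ratios scaling. Interferon-stimulated genes in blood endothelial cells stood at -0.89 and 0.47, the former at -0.47 with a minimum of 100 UMIs. Activation genes in these cells stood at 0.63 and -0.40, but at 0.63 and 0.28, on the same side, over members passing the free RNA rule. Barcodes over the mitochondrial limit, which entered no comparison, made up 15.2% (14.5 to 15.9) of the single-dose library and 16.6% (15.9 to 17.3) of the fractionated day 7 library. The control value was 5.49% (5.10 to 5.91) and that of the fractionated day 14 library 3.71%.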

How the results depend on the processing

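The alternatives over members passing the free RNA rule, without 8 stress-responsive members, for fibroblast and macrophage shares, and for named genes other than scaling and the stricter filter were chosen after seeing the data, as were all those for day 14 against control and for clusters 25 and 21. No paired analysis was possible because each group held 1 library. Of 801 list medians of the 4 planned comparisons under an alternative, 614 stayed within the counting interval, 179 moved beyond it and 8 with an interval excluding 0 changed sign, and in all 767 kept their sign. Of such values for day 14 against control, fibroblasts with cluster 25 and cluster 21, 362 stayed within the interval, 90 moved beyond it and 7 with an interval excluding 0 changed sign, and in all 432 kept their sign. For clusters 25 and 21 filter, doublets, resolution and class assignment were not changed, and no list median over passing members was formed from fewer than 3. The stress list kept its sign in 116 of 119 values of both sets. All 32 ratios of epithelial and immune shares under an alternative kept their sign. For 78 named genes, 359 log2 ratios were recomputed with the stricter filter, doublets kept, the lower resolution, each cell classed by its own marker score or every cell weighted equally, where these gave a value. All 359 kept their sign and 39 lay beyond the counting interval, most of them under equal weighting. There Ramp3 stood at 3.33 instead of 6.27 for fractions against control and Slamf7 at 7.27 instead of 5.64 for single dose against control. For day 14 against day 7 Krtdap stood at -1.62 instead of -2.73 and Grhl3 at -1.98 instead of -2.90. For day 14 against control Sprr1a stood at -1.17 instead of -2.44, Slurp2 at -1.96 instead of -3.25 and N5 at -1.33 instead of -2.54. With doublets kept Hspa1b stood at 7.07 instead of 7.94 for day 14 against day 7. At the lower resolution Slpi stood at 5.03 instead of 6.86 for single dose against control. With each cell classed by its own marker score Trh stood at 5.32 instead of 6.88 for day 14 against control. Scaling shifts all genes of a class alike and could not turn ratios of this size, so its 78 values, with 2 beyond the interval, say nothing on direction. Genes named for clusters 25 and 21 and members named from lists were not recomputed singly. Of 40 ratios of fibroblast and macrophage shares, 22 stayed within the counting interval, 15 moved beyond it and 3 changed sign. Depth limits the macrophage values, which rest on 207 control cells. Apart from named genes, the values beyond the interval follow, as median log2 ratios unless stated, and the cause was not tested. With the stricter cell filter, S phase genes were 0.91, G2/M genes 0.66, MHC class II genes 2.42, basal genes 0.47, differentiation genes -0.86 and wound keratins and alarmins -0.067 in epithelial cells for single dose against control. G2/M genes lay at -1.54 and inflammatory mediators -0.82 in endothelial cells for single dose against control. Hypoxia genes lay at -0.94 in epithelial cells for fractions against control. S phase genes lay at -0.18 and G2/M genes -0.72 in endothelial cells for fractions against control. S phase genes were -1.67, G2/M genes -1.37, interferon-stimulated genes -0.17, inflammatory mediators -3.18, basal genes -0.0055 (sign reversed), wound keratins and alarmins -1.59, hypoxia genes -0.78 and stress genes -1.59 in epithelial cells for fractions against single dose. Interferon-stimulated genes lay at 0.51 in epithelial cells for day 14 against day 7. Interferon-stimulated genes were 0.77 and stress genes 0.36 in epithelial cells for day 14 against control. Stress genes lay at -0.26 in fibroblast cells for day 14 against control. G2/M genes were -1.06, inflammatory mediators 0.12, stress genes 0.072 and activation genes 0.080 in endothelial cells for day 14 against control. Log2 ratios of epithelial shares were 0.26 for single dose against control and 1.40 for fractions against single dose. The log2 ratio of immune shares was 0.95 for day 14 against day 7. Log2 ratios of macrophage/monocyte shares were 4.12 for single dose against control, 1.61 for fractions against control (sign reversed), -2.51 for fractions against single dose and 0.59 for day 14 against day 7. With doublets kept, MHC class II genes were 2.02 in epithelial cells for single dose against control. S phase genes came to -0.34, G2/M genes -0.45 and inflammatory mediators -0.88 in endothelial cells for single dose against control. G2/M genes came to -1.61 and NRF2 targets 0.24 in macrophage cells for single dose against control. S phase genes measured 0.043 and G2/M genes -0.012 (sign reversed) in endothelial cells for fractions against single dose. G2/M genes measured -0.46 and angiogenesis genes 0.28 in endothelial cells for day 14 against day 7. G2/M genes gave -1.02 in endothelial cells for day 14 against control. G2/M genes showed -0.95 and lipid-associated genes 0.23 in macrophage cells for day 14 against control. At Leiden resolution 0.5, G2/M genes were -0.93 in endothelial cells for single dose against control. Interferon-stimulated genes came to 0.23, MHC class II genes -1.30 (sign reversed), NRF2 targets 0.83, stress genes -3.47, resident macrophage genes -2.27 and lipid-associated genes 0.76 in macrophage cells for single dose against control. G2/M genes lay at -0.30 in endothelial cells for fractions against control. Hypoxia genes were 0.078 in fibroblast cells for day 14 against control. G2/M genes were -0.66 in endothelial cells for day 14 against control. G2/M genes came to -1.06, MHC class II genes 0.10, NRF2 targets 0.13 and resident macrophage genes 0.40 in macrophage cells for day 14 against control. The log2 ratio of macrophage/monocyte shares was 3.30 for single dose against control. With each cell classed by its own marker score, MHC class II genes were 2.70, basal genes 0.11, differentiation genes -0.66 and NRF2 targets -0.28 in epithelial cells for single dose against control. Inflammatory mediators lay at -0.63 in endothelial cells for single dose against control. S phase genes gave -0.17 in endothelial cells for fractions against control. MHC class II genes lay at -0.89, basal genes 0.38 and NRF2 targets -0.14 in epithelial cells for fractions against single dose. Stress genes were -0.24 in fibroblast cells for day 14 against control. Inflammatory mediators were 0.17, stress genes 0.061 and activation genes 0.0033 in endothelial cells for day 14 against control. Log2 ratios of immune shares were -2.28 for fractions against single dose and 0.60 for day 14 against day 7. Log2 ratios of fibroblast shares were -2.81 for single dose against control, -2.55 for fractions against single dose and 5.33 for day 14 against day 7. Log2 ratios of macrophage/monocyte shares were 0.66 for fractions against control (sign reversed), -3.29 for fractions against single dose and 1.78 for day 14 against day 7. With median-of-ratios scaling, S phase genes were 0.57, G2/M genes 0.16, basal genes 0.094, differentiation genes -0.86, NRF2 targets -0.52, hypoxia genes -0.19 and stress genes -2.88 in epithelial cells for single dose against control. Hypoxia genes came to -0.93 in epithelial cells for fractions against control. Activation genes lay at -0.53 in endothelial cells for fractions against control. G2/M genes measured -0.97, basal genes 0.33, wound keratins and alarmins -1.27, hypoxia genes -0.60 and stress genes -1.68 in epithelial cells for fractions against single dose. G2/M genes gave 0.48, interferon-stimulated genes 1.02 and angiogenesis genes 0.38 in endothelial cells for fractions against single dose. Angiogenesis genes lay at 0.28 in endothelial cells for day 14 against day 7. Stress genes came to 0.29 in epithelial cells for day 14 against control. G2/M genes showed -0.54, p53 targets 0.46, inflammatory mediators 0.087, NRF2 targets 0.21, stress genes -0.32 and matrix proteases 0.23 in fibroblast cells for day 14 against control. MHC class II genes were 1.40, p53 targets 0.37, NRF2 targets 0.13, stress genes 0.12, resident macrophage genes 0.31 and lipid-associated genes 0.31 in macrophage cells for day 14 against control. NRF2 targets lay at 0.012, hypoxia genes 0.20, stress genes -3.81 and matrix proteases 0.15 in fibroblast and cluster 25 cells for single dose against control. NRF2 targets were 0.16 in cluster 21 cells for fractions against single dose. With a minimum of 100 UMIs, stress genes were -2.95 in epithelial cells for single dose against control. S phase genes showed -0.46 and interferon-stimulated genes -0.47 in endothelial cells for single dose against control. Inflammatory mediators came to -3.22 and matrix proteases 0.40 in macrophage cells for single dose against control. Differentiation genes lay at -0.500 and stress genes -4.42 in epithelial cells for fractions against control. S phase genes lay at 0.066 in endothelial cells for fractions against single dose. Interferon-stimulated genes measured 0.74, inflammatory mediators 4.14 and stress genes 4.16 in epithelial cells for day 14 against day 7. Interferon-stimulated genes gave 0.74 in epithelial cells for day 14 against control. The p53 targets lay at 0.29 in fibroblast cells for day 14 against control. G2/M genes lay at -0.19 in macrophage cells for day 14 against control. S phase genes were 0.20, G2/M genes 0.37 and inflammatory mediators 1.502 in fibroblast and cluster 25 cells for single dose against control. Interferon-stimulated genes showed -0.26, monocyte genes -1.76 and lipid-associated genes -0.73 in cluster 21 cells for fractions against single dose. Without the count minimum, stress genes were -2.53 in epithelial cells for single dose against control. Inflammatory mediators measured -0.23 in endothelial cells for single dose against control. MHC class II genes came to 0.24 and stress genes -3.42 in macrophage cells for single dose against control. Inflammatory mediators gave -4.15 and differentiation genes -0.28 in epithelial cells for fractions against control. Inflammatory mediators showed -2.01 and activation genes -0.63 in endothelial cells for fractions against control. Stress genes measured -1.67 in epithelial cells for fractions against single dose. Interferon-stimulated genes lay at 1.27 in epithelial cells for day 14 against day 7. Inflammatory mediators lay at 2.29 in endothelial cells for day 14 against day 7. Inflammatory mediators were 1.000 and differentiation genes -0.83 in epithelial cells for day 14 against control. Stress genes gave -0.24 in fibroblast cells for day 14 against control. Stress genes showed 0.23 in endothelial cells for day 14 against control. Inflammatory mediators came to -0.56 in macrophage cells for day 14 against control. Matrix genes lay at 0.028 in fibroblast and cluster 25 cells for single dose against control. MHC class II genes measured 0.59, p53 targets -0.36, hypoxia genes -0.67 and monocyte genes -1.43 in cluster 21 cells for fractions against single dose. With every cell weighted equally, S phase genes were 0.55, G2/M genes 0.12, interferon-stimulated genes 0.47, basal genes 0.30 and differentiation genes -0.62 in epithelial cells for single dose against control. S phase genes came to -0.38, G2/M genes -0.82, inflammatory mediators 0.082 (sign reversed), stress genes -2.54 and activation genes 0.94 in endothelial cells for single dose against control. G2/M genes were -0.78, interferon-stimulated genes -0.40, MHC class II genes 0.17, resident macrophage genes -3.20 and monocyte genes 3.72 in macrophage cells for single dose against control. G2/M genes came to -0.499, p53 targets -0.22, interferon-stimulated genes 0.504, basal genes 0.73, differentiation genes -0.55, wound keratins and alarmins -0.32, NRF2 targets -0.090, hypoxia genes -0.72 and stress genes -4.72 in epithelial cells for fractions against control. G2/M genes measured -0.23, stress genes -3.82 and activation genes -0.62 in endothelial cells for fractions against control. S phase genes measured -1.07, p53 targets -0.0012, G2/M genes -0.59, MHC class II genes -0.78, basal genes 0.64, differentiation genes 0.22, wound keratins and alarmins -0.84, NRF2 targets -0.13 and hypoxia genes -0.47 in epithelial cells for fractions against single dose. G2/M genes gave 0.46 and angiogenesis genes 0.38 in endothelial cells for fractions against single dose. S phase genes gave 0.57, p53 targets 0.39, G2/M genes 0.502, interferon-stimulated genes 0.68, MHC class II genes 0.57, inflammatory mediators 3.95, basal genes -0.063 (sign reversed), differentiation genes 0.12 (sign reversed), wound keratins and alarmins 1.85, NRF2 targets 0.031 and stress genes 4.21 in epithelial cells for day 14 against day 7. G2/M genes showed -0.12, interferon-stimulated genes 0.0095 and angiogenesis genes 0.31 in endothelial cells for day 14 against day 7. S phase genes showed -0.15 (sign reversed), G2/M genes 0.062, inflammatory mediators 0.29, differentiation genes -0.38 and stress genes 0.13 in epithelial cells for day 14 against control. Inflammatory mediators measured 0.088, stress genes -0.24 and matrix genes 0.20 in fibroblast cells for day 14 against control. S phase genes lay at 0.047 (sign reversed), G2/M genes -0.41, inflammatory mediators 0.74, stress genes -0.064 (sign reversed), activation genes 0.38 and angiogenesis genes -0.053 (sign reversed) in endothelial cells for day 14 against control. G2/M genes lay at 1.02, hypoxia genes 0.46, stress genes -3.53 and matrix proteases 0.65 in fibroblast and cluster 25 cells for single dose against control. Resident macrophage genes lay at 0.44 in cluster 21 cells for fractions against single dose. Over members passing the free RNA rule, inflammatory mediators were -2.29, p53 targets -1.52, basal genes 0.37, wound keratins and alarmins -1.44, NRF2 targets -0.24 and hypoxia genes 0.20 in epithelial cells for single dose against control. Stress genes lay at -2.46 in endothelial cells for single dose against control. G2/M genes were -0.75, p53 targets -1.52, interferon-stimulated genes -1.44, inflammatory mediators -3.73, NRF2 targets 0.066, hypoxia genes 1.39, matrix proteases 0.40 and resident macrophage genes -2.35 in macrophage cells for single dose against control. S phase genes were -1.09, G2/M genes -0.77, inflammatory mediators -2.53, differentiation genes -0.28, wound keratins and alarmins -2.21, NRF2 targets 0.16 and hypoxia genes -0.54 in epithelial cells for fractions against control. G2/M genes came to -0.36, p53 targets 0.52, inflammatory mediators -1.82, stress genes -5.53 and activation genes 0.28 (sign reversed) in endothelial cells for fractions against control. Basal genes lay at 0.17, wound keratins and alarmins -0.21, NRF2 targets 0.27 and stress genes -0.95 in epithelial cells for fractions against single dose. S phase genes came to 0.70, G2/M genes 0.79, inflammatory mediators -0.82, stress genes -0.60 and angiogenesis genes 0.75 in endothelial cells for fractions against single dose. Inflammatory mediators gave 1.43, wound keratins and alarmins 1.69, NRF2 targets -0.13 (sign reversed) and hypoxia genes 0.47 in epithelial cells for day 14 against day 7. S phase genes measured -0.067, G2/M genes -0.63, inflammatory mediators 2.16 and stress genes 4.93 in endothelial cells for day 14 against day 7. Inflammatory mediators showed 0.085 and p53 targets -0.40 (sign reversed) in epithelial cells for day 14 against control. S phase genes gave -0.26, p53 targets 0.25, interferon-stimulated genes 0.56, hypoxia genes 0.0071, matrix genes 0.44 and matrix proteases 0.41 in fibroblast cells for day 14 against control. Stress genes were 0.24 and activation genes 0.083 in endothelial cells for day 14 against control. G2/M genes measured -0.19, interferon-stimulated genes -0.15 (sign reversed) and inflammatory mediators -0.48 in macrophage cells for day 14 against control. S phase genes showed 0.015 and stress genes -3.78 in fibroblast and cluster 25 cells for single dose against control. G2/M genes gave 0.047 (sign reversed) and lipid-associated genes 1.01 in cluster 21 cells for fractions against single dose. Without 8 stress-responsive members, p53 targets were 0.073 in epithelial cells for single dose against control, -0.029 in epithelial cells for fractions against control, 0.59 in endothelial cells for fractions against control, 0.40 in epithelial cells for day 14 against day 7, 0.93 in fibroblast cells for day 14 against control, 0.74 in endothelial cells for day 14 against control, 0.42 in fibroblast and cluster 25 cells for single dose against control and -0.37 in cluster 21 cells for fractions against single dose. Without thinning, shares of epithelial cells with a UMI of Mki67 or Top2a were 31.7%, 47.5%, 16.6% and 31.03% in group order. With cluster 25 counted as fibroblast, log2 ratios of fibroblast shares were -2.16 for single dose against control, -5.32 for fractions against control, -3.16 for fractions against single dose and 5.37 for day 14 against day 7. With cluster 21 counted as macrophages, log2 ratios of macrophage/monocyte shares were 1.56 for fractions against control (sign reversed), -2.32 for fractions against single dose and 0.62 for day 14 against day 7.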

Other observations

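The comparison of fractionated day 14 with control cells and the readings of clusters 25 and 21 were chosen after seeing the data, as were all tests given here except those on free RNA and on the mitochondrial filter. In fibroblasts at day 14, p53 targets were higher than in the control at 0.53 (0.48 to 0.75), and at 0.93 (0.68 to 1.03) without the 8 stress-responsive members. Over members passing the free RNA rule these medians were 0.25 and 0.53 (0.49 to 0.61). In the same cells 32 of 34 interferon-stimulated genes were higher at a median of 0.75 (0.67 to 0.86). Matrix and myofibroblast genes stood at 0.34 (0.27 to 0.40), matrix proteases at 0.30 (0.25 to 0.34), NRF2 targets at 0.27 (0.22 to 0.35), hypoxia and glycolysis genes at 0.16 (0.080 to 0.28), inflammatory mediators at 0.15 (0.10 to 0.33), S phase genes at -0.061 (-0.15 to 0.021) and G2/M genes, of which 2 passed the free RNA rule, at -0.48 (-0.54 to -0.24). Passing hypoxia and glycolysis genes stood at 0.0071 and passing S phase genes at -0.26, and matrix and myofibroblast genes stood at 0.20 with every cell weighted equally. The hormone precursor gene Trh was 118-fold (45.8 to 434) higher, the efflux transporter Abcb1a 40.8-fold (30.5 to 55.9) and Ccn5 32.1-fold (29.5 to 35), and Lpar4 was 6.27-fold (5.53 to 7.12) lower, Dlk1 6.86-fold (5.41 to 8.79) and Ppp2r2b 4.66-fold (3.87 to 5.62). Beside these the stress list was at -0.25 (-0.26 to -0.24). With each cell classed by its own markers the log2 ratio of Trh was 5.32 instead of 6.88. Cluster 4, led by Ccn5, held most day 14 fibroblasts, and clusters 0 and 11 most control ones. In blood endothelial cells the p53 targets Phlda3, Aen and Ccng1 were 10.1-fold (8.95 to 11.4), 11.3-fold (8.18 to 16.2) and 8.58-fold (6.70 to 11.1) higher, G2/M genes stood at -0.89 (-0.98 to -0.76), interferon-stimulated genes at 0.74 (0.58 to 0.81) and the stress list at 0.12 (0.10 to 0.13). With every cell weighted equally these G2/M and stress medians were -0.41 and -0.064. Csf3 was 5.38-fold (4.02 to 7.24) lower, Dmrta1 5.05-fold (3.19 to 8.11) and N5 5.82-fold (3.42 to 10.2). In epithelial cells the cell cycle inhibitor Cdkn2a was 22.5-fold (17.5 to 29.3) higher, Hist1h2ah 18.5-fold (14.4 to 24.04) and Il24 15.1-fold (9.83 to 23.6), with interferon-stimulated genes at 1.21 (0.92 to 1.45) and the stress list at 0.32 (0.29 to 0.35), with 2 and 1 of their members passing that rule. With the stricter filter the former stood at 0.77. Differentiation genes were lower at -0.86 (-1.04 to -0.83), or at -0.38 with every cell weighted equally, with Sprr1a 5.44-fold (5.17 to 5.72) lower, the sterol synthesis gene Msmo1 9.25-fold (7.78 to 11.1) and Slurp2 9.54-fold (5.15 to 19.97). With every cell weighted equally the log2 ratios were -1.17 instead of -2.44 for Sprr1a, -1.96 instead of -3.25 for Slurp2 and, in the endothelial cells, -1.33 instead of -2.54 for N5. In macrophages all 7 measured MHC class II genes were higher at 1.26 (1.11 to 1.36), although only 1 passed the free RNA rule. At the lower clustering resolution this median was 0.10. G2/M genes stood at -0.63 (-0.83 to -0.37), or at -0.19 over passing members, and the stress list stood at -0.023 (-0.080 to 0.011), beside a median of all genes of -0.14. Slfn4 was 20.02-fold (7.75 to 73.9) higher, the lipid carrier Apoe 7.02-fold (6.65 to 7.41) and the uncertain symbol Y_RNA 29.1-fold (5.13 to 1158), and Slc15a2 was 9.21-fold (5.67 to 15.3) lower, Gprc5d 7.81-fold (4.46 to 14.1) and Cdkn2c 5.75-fold (3.97 to 8.36).

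Cluster 25 scored highest for fibroblasts but had Chrdl2, a muscle satellite marker, and no fibroblast marker among its 10 leading genes, and it held 6.34% of single-dose cells and 1 control cell. Counted as fibroblasts, the single-dose cells had higher inflammatory mediators than control fibroblasts, at 2.30 (1.79 to 2.89), and higher G2/M genes, of which 1 passed the free RNA rule, at 1.41 (1.07 to 1.59), beside a stress list at -3.67 (-3.72 to -3.61). At a minimum of 100 UMIs the mediator and G2/M medians were 1.502 and 0.37. The chemokine Cxcl6 was at least 6144-fold higher, Lcn2 7223-fold (4378 to 12907) and Chrdl2 1600-fold (811 to 3710), all 3 being leading genes of cluster 25. Atf3 was 601-fold (452 to 818) lower, Fos 33.9-fold (32.3 to 35.7) and Jun 32.9-fold (31.1 to 34.8). The median of all genes lay at 0.15 in this comparison. Cluster 21, led by MHC class II genes, could be compared between the day 7 irradiated libraries. Inflammatory monocyte genes were lower there after fractions than after the single dose at -2.22 (-2.56 to -1.76), and inflammatory mediators at -2.43 (-3.15 to -2.02), but only 1 and 2 of their members passed the free RNA rule. Without the count minimum the former stood at -1.43. The stress list stood at -2.16 (-2.35 to -1.94), and RT1-Bb was 4.09-fold (3.87 to 4.33) higher, Axl 4.99-fold (3.82 to 6.58) and Dgat2 6.51-fold (4.41 to 9.83), beside a median of all genes of -0.12.

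The stress list was lower in every class read at day 7 after radiation, at medians of -2.65 or below, and lay between -0.48 and 0.54 at day 14. Free RNA from fibroblasts was argued against as the whole source of these transcripts in control epithelial cells, where the list reached 31.1% of its fibroblast level while 4 fibroblast markers reached 1.24%. Handling or dissociation that differed between libraries would lower the list in all classes, and it was -1 or lower in 17 of 17 pairs of class and day 7 irradiated library. Some of these pairs held under 200 cells in a library, down to 51 macrophages in the fractionated day 7 library. A response to radiation at day 7 predicts the same 17 of 17, so handling and radiation cannot be told apart with 1 library per group. Groups that move with the list, such as inflammatory mediators in epithelial cells, may share either cause. Mediators did not move with it in single-dose fibroblasts with cluster 25 counted, at 2.30 against -3.67. In single-dose blood endothelial cells they stood at 0.082 with every cell weighted equally.

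In stress and inflammatory genes of epithelial and blood endothelial cells, the fractionated day 14 library lay closer to the control than to the fractionated day 7 library. The stress list stood at 0.32 and 0.12 against the control and at 4.46 and 3.58 against day 7, in that order of classes. Inflammatory mediators stood at 0.55 and 0.38 against the control and at 4.55 and 3.15 against day 7. No comparison with the single-dose library was made. A mislabelled unirradiated library was argued against by p53 targets without the stress-responsive members in its fibroblasts, at 0.93 (0.69 to 1.02) above the control, and in its blood endothelial cells, at 0.74 (0.46 to 1.31). Over members passing the free RNA rule these were 0.53 (0.49 to 0.61) and 1.37 (1.26 to 1.77), although the whole p53 list in fibroblasts stood at 0.25 over such members. In epithelial cells and macrophages the same list stood at 0.16 (0.032 to 0.25) and 0.076 (-0.13 to 0.26). Over passing members it stood at -0.23 (-0.44 to 0.024) and -0.044 (-0.31 to 0.38). These medians lay within the 0.3 of 0 that a mislabelled library predicted for fibroblasts, so the p53 argument rests on the first pair of classes. Some cell shares, which the prediction did not cover, also differed from the control. Muscle satellite cells were 8.48-fold (6.77 to 10.7) lower, epithelial cells 5.04-fold (4.545 to 5.61) lower and immune cells 3.90-fold (3.48 to 4.39) higher. Fibroblasts had a ratio of 1.04-fold (0.988 to 1.09). A p53 response at day 14 is a candidate explanation of the median in fibroblasts, found and examined on the same data. Whether it was present at day 7 could not be read, with 54 fibroblasts in the fractionated day 7 library. Time after exposure stays open and untested.

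Fibroblasts were scarce in both day 7 irradiated libraries. Dilution by epithelial and immune cells was argued against as the whole cause by fibroblasts per mural cell, which dilution alone would leave near the control, here taken as within 2-fold. After fractions they stood at a log2 ratio of -5.25 against the control and of -4.86 with cluster 25 counted. After the single dose these ratios were -4.87 and -1.72 (-1.93 to -1.504) in the same order. The 2-fold bound replaced, after the values were seen, a 4-fold bound that the last value does not reach. The argument against dilution after the single dose is thus weaker with cluster 25, whose identity stays open, counted. The mural count left out the unnamed cluster 24, which scored highest for mural cells. It held 304 control, 47 single-dose and 39 fractionated day 7 cells. Counting these as mural would bring the ratios nearer to the control, by an amount not computed. The fibroblast counts left out the shallow unnamed cluster 23, which scored highest for fibroblasts. It held 565 control, 8 single-dose and 9 fractionated day 7 cells. Counting those as fibroblasts would take the single-dose ratios further from the control, also by an amount not computed. Loss through the mitochondrial filter was argued against by the left-out barcodes, whose 4 fibroblast markers reached at most 11.5% of the level in kept control cells, and counting cluster 25 as fibroblast still left log2 share ratios of -2.16 or lower. Lower release of fibroblasts during dissociation stays open, because only 1 library per group was made and no value bounds it, as does radiation, which the design names and which was not tested.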
